A study of Rattus norvegicus with 14 samples.

How the data were processed

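RNA of the lateral prostate of 14 male Noble rats, aged 48 weeks per the labels, had been measured on Affymetrix arrays, 1 array per rat. The labels put 4 arrays in the control group, 4 in the group given testosterone and estradiol (T+E2), 3 in the group given testosterone and low bisphenol A (T+lowBPA) and 3 in the group given testosterone and high bisphenol A (T+highBPA). Per the labels' protocols, control rats carried empty capsules and treated rats carried capsules for 32 weeks. The capsules held 30 mg testosterone with 15 mg estradiol, 15 mg bisphenol A or 320 mg bisphenol A. RNA was isolated with TRIzol and amplified with a whole-transcriptome kit, per the labels' protocols.

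The deposited values are on a log2 scale and were made with RMA, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of a probe set, so differences between arrays in overall brightness had been removed before deposit. Its version, the probe set definition and the genome build are not given in the sources used here. The deposited log2 values ran from 2.3 to 13.65, and array medians ran from 6.38 to 6.46. Arrays carry no read depth, and the number of arrays limits the precision. The table held 17802 probe sets, of which 16134 had 1 gene symbol, 0 had several and 1668 had none in the annotation used here. Each symbol had 1 probe set, so averaging the probe sets of a gene moved nothing. Symbols were brought up to date through the gene number of the probe set where the RefSeq gene table of assembly GRCr8 held the platform's symbol as symbol or synonym. This updated 3127 symbols, and 16008 of the named probe sets matched a gene number of that table. No value was filtered out, and probe sets without a symbol entered only an alternative.

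Differences between groups were fitted with limma 3.58.1 in R 4.3.3. Each gene had 1 coefficient per group over all 14 arrays, with 10 residual degrees of freedom and an empirical Bayes prior worth 4.13 more. The groups shared 1 estimate of the spread. All 6 pairs of groups were compared, two-sided, with Benjamini-Hochberg adjustment over 16134 genes within each comparison. A gene is called changed when its adjusted p is below 0.05. A difference is the mean of the first group minus that of the second, and its 95% interval comes from the moderated standard error. Every adjusted p of a single gene in the text is limma's. Values of a group are given as mean ± SD over its arrays.

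Before the data were examined, 36 gene lists were fixed: 18 functional lists and 18 lists of cell or tissue markers, with 891 entries, of which 773 were measured. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 36 lists within each comparison. Camera with the correlation estimated per list and fry were alternatives. The topic of the list of HNF4A and liver-type targets is that of the study itself, so its result is not independent evidence of a direction. The genes named were also chosen by a rule fixed at that time. Against control, these are the 8 largest changes in each direction among called genes whose arrays do not overlap between the groups, leaving out serial symbols, and between treated groups the 5 largest. Where no gene was called, the 3 smallest p values in each direction are given as values. For each list described, up to 4 members with the smallest p are named. The genes Hnf4a, Esr1, Esr2, Prlr, Pgr, Mki67, Pbsn, Cd4 and Cd8a were followed in every comparison. Other genes, named in the closing observations or beside a count, were chosen after their values were seen.

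The fits were tested on simulated data made from the real means and spreads with 200 changed genes. For T+E2 minus control, 95.4% of 65 genes changed 2-fold were recovered over 16134 genes, and 72.1% of 68 genes changed 1.5-fold. For T+highBPA minus T+lowBPA the shares were 92.4% of 66 genes and 47.4% of 57 genes. A simulated shift of 0.3 on the log2 scale in 1 list was called by camera in 6 of 6 comparisons, with 0 other lists called. The simulated genes had independent noise and 1 spread for all groups, with no outlying array and no other tissue. The shares can therefore overstate recovery on the real arrays, where few calls do not show few differences. The list check does not show that the preset correlation suits the real lists.

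Alternatives fixed beforehand were a filter on dim genes, all probe sets, cyclic loess, centring on the array median, only the compared groups in the fit, an intensity trend with robust empirical Bayes, array weights, the replicate number as a block, other thresholds, and leaving out each array in turn. After the data had been seen, 3 alternatives were added: quantile normalization, leaving out the 3 arrays with the highest ventral prostate genes, and the mean of those genes as a covariate. Also written after the data had been seen were 3 gene sets, of 9 secretory genes of the ventral prostate, 38 genes of gut and goblet type, and 18 abundant gut transcripts. Figures were drawn with matplotlib.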

Results

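Gene expression was measured in the lateral prostate, the lobe in which Noble rats develop preneoplastic lesions under combined sex hormones. The series asks what bisphenol A (BPA), a plastic monomer with weak estrogenic activity, does to the transcriptome of this lobe in testosterone-treated rats. The groups were control (n = 4), testosterone plus estradiol (T+E2, n = 4), testosterone plus low BPA (T+lowBPA, n = 3) and testosterone plus high BPA (T+highBPA, n = 3). No group given testosterone alone was analysed here, so a difference between a BPA group and control holds the difference of both compounds. The labels name each sample as a rat, and the p-values measure the spread between these rats.

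Arrays of a group correlated across genes at 0.956 to 0.994 in control, 0.979 to 0.99 in T+E2, 0.986 to 0.991 in T+lowBPA and 0.982 to 0.989 in T+highBPA. Control replicate 4 stood apart. Its mean correlation with the other controls was 0.962, its nearest array was T+highBPA replicate 2 at 0.985, and its array weight was 0.26. The mean of 9 secretory genes of the ventral prostate, among them Sbp, Scgb1d2 and Klk1c9, was 11.95 in control replicate 4 against 5.17 to 5.49 in the other controls. It was 11.8 in T+E2 replicate 2, 12.17 in T+highBPA replicate 2, 10.06 and 9.06 in T+highBPA replicates 1 and 3, and 6.44 to 6.68 in T+lowBPA. The mean of these genes was 10.43 ± 1.59 in T+highBPA and 7.02 ± 3.29 in control (SD, exact permutation p = 0.114). Markers of skeletal muscle varied within groups too, from 6.88 to 9.62 in control and from 6.28 to 8.46 in T+highBPA. In control, T+E2, T+lowBPA and T+highBPA they were at 6.88, 6.36, 7.12 and 6.31 in replicate 1. In replicate 3 they were at 9.21, 9.05, 9.79 and 8.46, and in replicate 2 at 9.62, 7.82, 6.79 and 6.28. Replicate 1 thus lay below replicate 3 in every group, and the cause of this was not tested. Over the 14 arrays, a look chosen after seeing the data, deviations of the skeletal muscle mean from the group means correlated with those of fatty acid oxidation (0.889), oxidative phosphorylation (0.884), smooth muscle (0.83), adipocyte (0.776), NRF2 (0.766), urothelium (0.679), basal epithelium (0.631) and HNF4A targets (-0.64). Those of the ventral prostate mean correlated with cholesterol synthesis (0.903), ER stress (0.565) and endothelium (-0.909). They also ran against T cell (-0.687), B cell (-0.685), macrophage (-0.665), basal epithelium (-0.551) and antigen presentation (-0.525). The seminal vesicle and ventral prostate list (0.985) and the androgen-responsive list (0.964), which hold some of these genes, followed it too. Because control replicate 4 departs from its group, the counts of called genes and lists without it are given for each comparison.

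**Figure D1:**
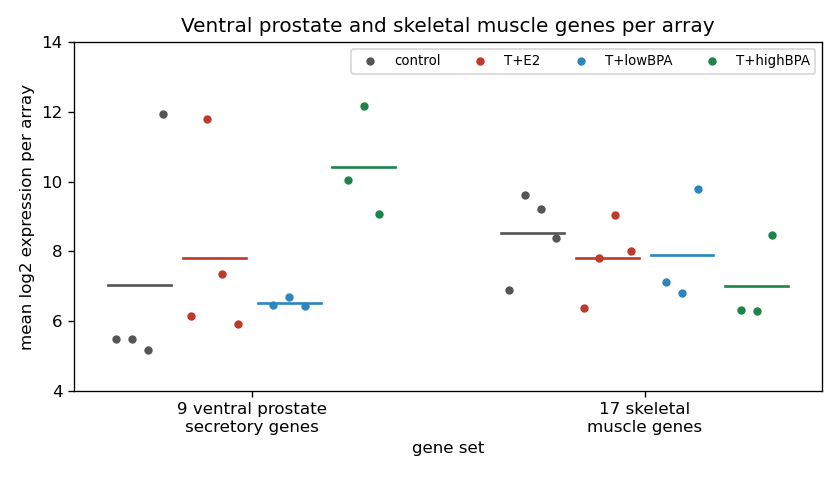
Mean log2 expression per array (y axis) of 9 ventral prostate secretory genes and of the skeletal muscle list (x axis), by group. Points are arrays and lines are group means; control replicate 4 lies at 11.95 for the ventral prostate genes, while the other controls lie between 5.17 and 5.49.

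The comparison of T+E2 with control shows the transcriptome of the hormone combination. Gucy2f, a guanylyl cyclase known from photoreceptors, rose 68.2-fold, from 4.03 ± 0.06 to 10.12 ± 0.29 on the log2 scale (SD, n = 4 each, adjusted p = 5.26e-13). Clca1, a protein secreted by goblet cells, rose by 4.97 on the log2 scale to 13.21 ± 0.06, from 8.24 ± 2.16 in control. Adgrg7, an adhesion receptor, rose 21.3-fold, Syt10, a vesicle calcium sensor, 17.5-fold, and Ccl25, a chemokine of thymus and small intestine, 12.7-fold (adjusted p = 7.52e-06, 3.53e-09 and 1.09e-06). The trace amine receptor Taar1 rose by 3.52 ± 0.18 (SE), Clca4 by 2.88 ± 0.26 and the zinc finger gene Zbtb40 by 2.86 ± 0.23. In the other direction, the cadherin Cdh7 fell from 7.37 ± 0.26 to 4.14 ± 0.56 (SD, adjusted p = 1.25e-06). The syntrophin Sntg1 fell by 1.77, the fibrinogen chain Fgg by 1.70 and the glucuronosyltransferase Ugt2b10 by 1.61. Upk1a, a uroplakin, fell by 1.33, the adhesion molecule Nrcam by 1.25 and the Wnt inhibitor Wif1 by 1.23. Krt15, a basal keratin, fell by 1.62 ± 0.40 (SE) with an adjusted p of 0.0415, and this call was lost under cyclic loess (0.0508). It was also lost without control replicate 2 or 3, any T+E2 replicate, T+lowBPA replicate 1 or 2, or T+highBPA replicate 2 (adjusted p = 0.0537 to 0.132).

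In total 521 of 16134 genes were called, 284 higher and 237 lower in T+E2. Their arrays did not overlap between the groups for 490, and 93 rose and 19 fell at least 2-fold. The count fell to 282 without T+E2 replicate 4, 295 without control replicate 2, 315 without control replicate 3 and 317 without T+E2 replicate 2, and was 599 without control replicate 4.

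**Figure D2:**
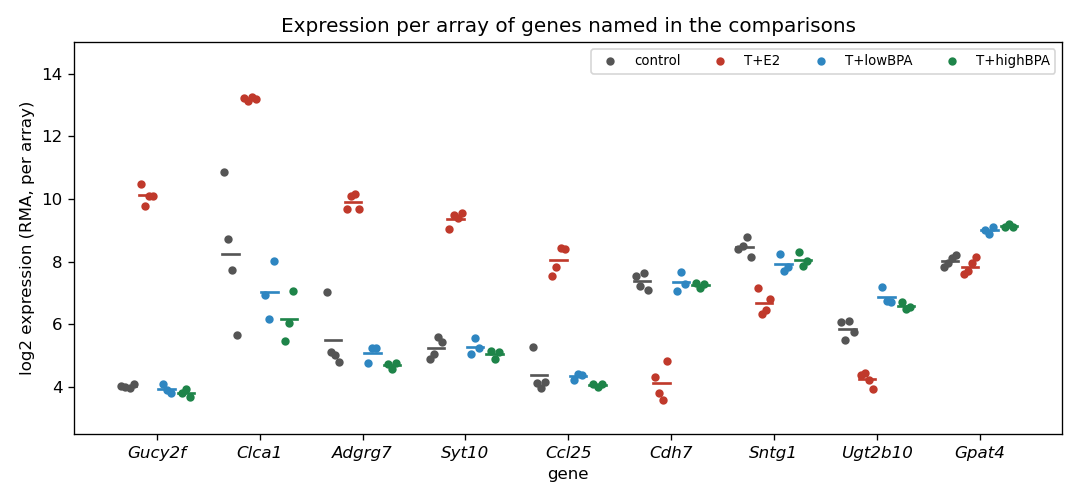
Log2 expression per array (y axis) of 9 genes (x axis) in the 4 groups. Points are arrays and lines are group means; Gucy2f has a mean of 10.12 in T+E2 against 4.03 in control, while Gpat4 has a mean of 9.14 in T+highBPA against 8.02 in control.

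Genes of smooth muscle fell in T+E2. Of 19 measured members 6 were called lower and 0 higher, or 11 lower when adjusted over the list alone, and the median difference was -0.52 (camera adjusted p = 1.33e-08, or 0.795 with an estimated correlation). The contractile genes Cnn1, Actg2 and Pgm5 fell by 0.59, 0.78 and 0.75. Each of these 3 gene calls ended without control replicate 2 or 3 or T+E2 replicate 2 or 3 (limma adjusted p = 0.0656 to 0.109), that of Actg2 also without T+E2 replicate 1 (0.0501), and that of Cnn1 under cyclic loess (0.0522). The 6 called members became 0 without control replicate 2 or 3 or T+E2 replicate 2, 2 without T+E2 replicate 3 and 3 without T+E2 replicate 1 or 4. The list call held without control replicate 4 (adjusted p = 1.13e-08). Within groups the mean of this list followed that of the skeletal muscle markers (correlation 0.83), which was 7.81 ± 1.11 in T+E2 and 8.52 ± 1.21 in control (SD). Fatty acid oxidation and PPARA genes shifted down, with a median of -0.15 over 25 members and 3 called lower, or 4 when adjusted over the list alone. The enzymes Ehhadh, Acadm and Acaa2 fell by 0.62, 0.56 and 0.61 (list adjusted p = 0.0298, or 0.795 with an estimated correlation). Their own calls ended without control replicate 3 or T+E2 replicate 2 or 4 (limma adjusted p = 0.0597 to 0.1), and that of Acadm also without control replicate 2 (0.105) or T+E2 replicate 1 (0.0728). The call of Acaa2 held without control replicate 1 or T+E2 replicate 3 and ended without any other array (0.0503 to 0.124, and 0.0602 without control replicate 4). Without control replicate 2 or T+E2 replicate 1, 1 member of the list was called. Oxidative phosphorylation shifted down by a median of -0.14 over 28 members, of which 0 were called lower. Its 1 called member, also the only one when adjusted over the list alone, the complex I subunit Ndufa1, rose by 1.24 (list adjusted p = 0.0328, or 0.799 with an estimated correlation). Without control replicate 1 or T+E2 replicate 3, 1 member was called lower as well. The mean of this list and that of fatty acid oxidation also followed the skeletal muscle markers within groups (correlation 0.884 and 0.889).

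Antigen presentation shifted up in T+E2 with a median of 0.18, with 0 of 26 members called, and interferon response with a median of 0.17, with 1 of 34 called, the same counts as when adjusted over each list alone (adjusted p = 0.0298 each, or 0.795 with an estimated correlation). The called member was Herc6, higher by 0.82, and its call ended without control replicate 2 (limma adjusted p = 0.0506) or T+E2 replicate 2 (0.0535). B cell and plasma cell markers shifted up with a median of 0.26 over 18 members (adjusted p = 0.032, or 0.795 with an estimated correlation). Its 1 called member, Derl3, a component of endoplasmic reticulum degradation, fell by 0.86. The call of Derl3 ended without control replicate 2 (limma adjusted p = 0.106) or 4 (0.0619) or T+E2 replicate 1, 2 or 4 (0.0912, 0.0893 and 0.07). Adjusted over that list alone, 3 rose and 1 fell. Without control replicate 1, 4 interferon genes were higher, and 4 B cell genes were higher and 1 lower, and without control replicate 4, 1 interferon gene was higher and 1 lower. These 3 immune calls ended without control replicate 4 (adjusted p = 0.666, 0.132 and 0.206), as did those of fatty acid oxidation (0.0854) and oxidative phosphorylation (0.195). The last 2 also ended under cyclic loess (0.0712 and 0.182) and quantile normalization, chosen after seeing the data (0.0547 and 0.143). The 6 called lists became 13 without control replicate 1, 1 without control replicate 3 and 2 without control replicate 4.

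Lists that were not called held single large changes. In steroid and xenobiotic metabolism, 2 of 28 members rose: Cyp17a1, the 17-hydroxylase and lyase of androgen synthesis, 6.96-fold, and Hsd11b2, which inactivates glucocorticoids, 4.14-fold. In NRF2 and oxidative stress, 2 of 24 rose, the cystine transporter Slc7a11 by 2.78 and the glutathione transferase Gsta3 by 0.84. Among estrogen-responsive genes, 2 of 31 rose and 1 fell, with Muc1 higher by 0.56, Fhl2 higher by 0.58 and Rerg lower by 0.51. The call of Muc1 ended without control replicate 2 (limma adjusted p = 0.054). That of Fhl2 ended without control replicate 1, 2 or 3, T+E2 replicate 2, 3 or 4, T+lowBPA replicate 1 or 2 or T+highBPA replicate 1 (0.0512 to 0.0905), and that of Rerg without any array but control replicate 4 and T+highBPA replicate 3 (0.0519 to 0.112). Adjusted over that list alone, 5 rose and 2 fell. The protease Tmprss2 and the prostaglandin dehydrogenase Hpgd, of the androgen-responsive list, rose by 1.04 and 1.24. Elf5, a STAT5-linked transcription factor, fell by 0.97. Prlr, the prolactin receptor gene, was not called, but was higher by 1.82 without control replicate 4 (adjusted p = 0.0165). The HNF4A and liver-type list was not called (0 of 36 members, median 0.06, adjusted p = 0.216), and Hnf4a itself was at 5.72 ± 0.10 in T+E2 and 5.76 ± 0.49 in control (adjusted p = 0.933).

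The comparison of T+lowBPA with control asks what low BPA with testosterone did. Gpat4, an enzyme of the first step of glycerolipid synthesis, rose 1.97-fold from 8.02 ± 0.17 in control (SD, n = 4; n = 3 in T+lowBPA). The glycerol kinase family gene Gk5 rose 2.25-fold and the phosphatidylinositol kinase Pi4k2b 1.52-fold (limma adjusted p = 0.0253 each). These were the 3 called genes, with 1225 at an unadjusted p below 0.05. All 3 calls were lost without control replicate 1 or 2 or any of the 3 T+lowBPA arrays, with adjusted p of 0.0572 to 0.194, and that of Gk5 also without T+highBPA replicate 1 (0.0535). With the replicate number as a block, the calls of Gk5 and Pi4k2b ended as well. Without control replicate 1, 1 other gene was called, lower in T+lowBPA, and without control replicate 2 or a T+lowBPA array 0 were. Without control replicate 3 there were 8. Without control replicate 4 there were 14, of which 10 were higher, among them the protocadherin Pcdh20 (adjusted p = 0.00176), and 4 lower, among them the glypican Gpc3 (0.0229).

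Basal epithelium shifted down in T+lowBPA, with 16 of 17 members below control and a median of -0.09 (adjusted p = 0.000202, or 0.453 with an estimated correlation). Its members Dsc3, Itgb4 and Tp63 differed by -0.41, -0.32 and -0.39, and 0 were called, or 1 lower when adjusted over the list alone. Smooth muscle shifted down by a median of -0.20 over 19 members, 0 of them called in either way (adjusted p = 0.000589, or 0.748 with an estimated correlation). The skeletal muscle markers, which both lists followed within groups (correlation 0.631 for basal epithelium and 0.83 for smooth muscle), were at 7.90 ± 1.64 in T+lowBPA and 8.52 ± 1.21 in control (SD). T+lowBPA replicates 1 and 2, at 7.12 and 6.79 for these markers, were at 8.23 and 8.17 for smooth muscle, and replicate 3, at 9.79, was at 8.63, inside the control range of 8.16 to 8.84. Endothelium shifted up by 0.25 over 14 members, among them Cdh5 with 0.48 and Sox18 with 0.41, and again 0 were called in either way (adjusted p = 0.0034, or 0.748 with an estimated correlation). The endothelial call ended without control replicate 4 (adjusted p = 0.135), and within groups this list ran against the ventral prostate mean (correlation -0.909). The 3 called lists became 13 without control replicate 1, 7 without control replicate 2, 9 without control replicate 4, and 5 and 7 without T+lowBPA replicates 1 and 3.

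The comparison of T+highBPA with control concerns the higher BPA load. Gpat4 was its 1 called gene and rose 2.17-fold to 9.14 ± 0.04 (SD, n = 3, limma adjusted p = 0.00838), with 1394 genes at an unadjusted p below 0.05. In this comparison Gk5 differed by 0.75 (adjusted p = 0.288) and Pi4k2b by 0.30 (0.37). The call of Gpat4 was lost without control replicate 2 (0.0543) or any T+highBPA array (0.0599 to 0.103). Without control replicate 4, 12 genes were called, 10 higher and 2 lower. Scgb2a1 and Sbp, both ventral prostate secretory genes, were then higher by 3.23 and 5.17, and Tmem45a2 lower by 1.04. Without control replicate 1 there were 3.

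In T+highBPA 13 lists were called by camera, 8 up and 5 down, and 0 with an estimated correlation. None of their members was called over all genes. Interferon response had a median of 0.28 with 28 of 34 members higher, of which 7 rose when adjusted over the list alone (adjusted p = 2.48e-08, or 0.371 with an estimated correlation). Isg15, Mx2 and Oas1b differed by 0.96, 1.20 and 0.86. Oxidative phosphorylation had 27 of 28 members higher with a median of 0.20 (adjusted p = 2.48e-08, or 0.446 with an estimated correlation). Fatty acid oxidation and PPARA shifted up by 0.16, ER stress and protein secretion by 0.15, luminal epithelium by 0.18 and macrophage by 0.13 (adjusted p = 0.00108, 5.98e-05, 0.00142 and 0.025). With an estimated correlation these p values were 0.435, 0.371, 0.525 and 0.724, and the macrophage call ended without control replicate 4 (adjusted p = 0.999). The luminal call ended with the ventral prostate mean as a covariate (0.142), and quantile normalization ended that of luminal epithelium (0.0694), ER stress (0.182) and macrophage (0.163), both settings chosen after seeing the data. Within groups the ER stress list followed the ventral prostate mean (correlation 0.565), which was 10.43 in T+highBPA and 7.02 in control. With the covariate its adjusted p was 0.0494. The androgen-responsive and prostate secretory list and the seminal vesicle and ventral prostate list shifted up (adjusted p = 0.0105 and 0.0311, or 0.226 each with an estimated correlation). They hold the ventral prostate genes Sbp, Scgb2a1 and Scgb1d4, which differed by 3.74, 2.36 and 3.97. Quantile normalization ended both calls (0.197 and 0.0639). Tgm4, a transglutaminase secreted by the prostate, was at 8.28 ± 1.78 against 11.82 ± 0.46 in control (SD, limma adjusted p = 0.358). Adjusted over each list alone, 2 fatty acid oxidation genes and 2 of the 12 measured seminal vesicle genes rose, 1 of the 23 androgen-responsive genes rose and 1 fell, and 0 changed in the remaining raised lists apart from interferon. The androgen-responsive call ended under cyclic loess (adjusted p = 0.0958) and with the covariate (0.142), and the macrophage call under cyclic loess (0.14) and with the replicate block (0.43). Without control replicate 4, 15 lists were called.

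Basal epithelium was lower in all 17 members in T+highBPA, with a median of -0.21 (adjusted p = 1.54e-05, or 0.171 with an estimated correlation). Urothelium, with 11 measured members of which 2 fell when adjusted over the list alone, shifted down with Gata3 at -0.98 and Upk1b at -1.39 (adjusted p = 0.00203, or 0.153 with an estimated correlation). Smooth muscle had a median of -0.22 (adjusted p = 0.00879, or 0.552 with an estimated correlation), and its call ended with the ventral prostate covariate (0.435) and without the 3 arrays highest in ventral prostate genes (0.0557), both chosen after seeing the data. Skeletal muscle, with 17 members, had a median of -1.32 (adjusted p = 5.9e-06, or 0.525 with an estimated correlation), beside the spread of these markers within both groups. Urothelium, basal epithelium and smooth muscle followed it within groups (correlation 0.679, 0.631 and 0.83), and its mean was 7.01 ± 1.25 in T+highBPA and 8.52 ± 1.21 in control (SD). Basal epithelium also ran against the ventral prostate mean within groups (correlation -0.551), and with that mean as a covariate its adjusted p was 0.0324. The HNF4A and liver-type list was lower in 30 of 36 members with a median of -0.10 (adjusted p = 0.00393, or 0.371 with an estimated correlation). Its members Fgb, Fga and G6pc1 encode fibrinogen chains and glucose 6-phosphatase and differed by -0.27, -0.25 and -0.24. Its call ended under cyclic loess (adjusted p = 0.294) and under quantile normalization, chosen after seeing the data (0.389). The topic of this list is the study's own, so its direction is not independent evidence. Adjusted over the list alone, 0 members changed in it, or in the other 3 lists lowered here besides urothelium. Hnf4a differed by -0.07 (95% interval -0.49 to 0.35).

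**Figure D3:**
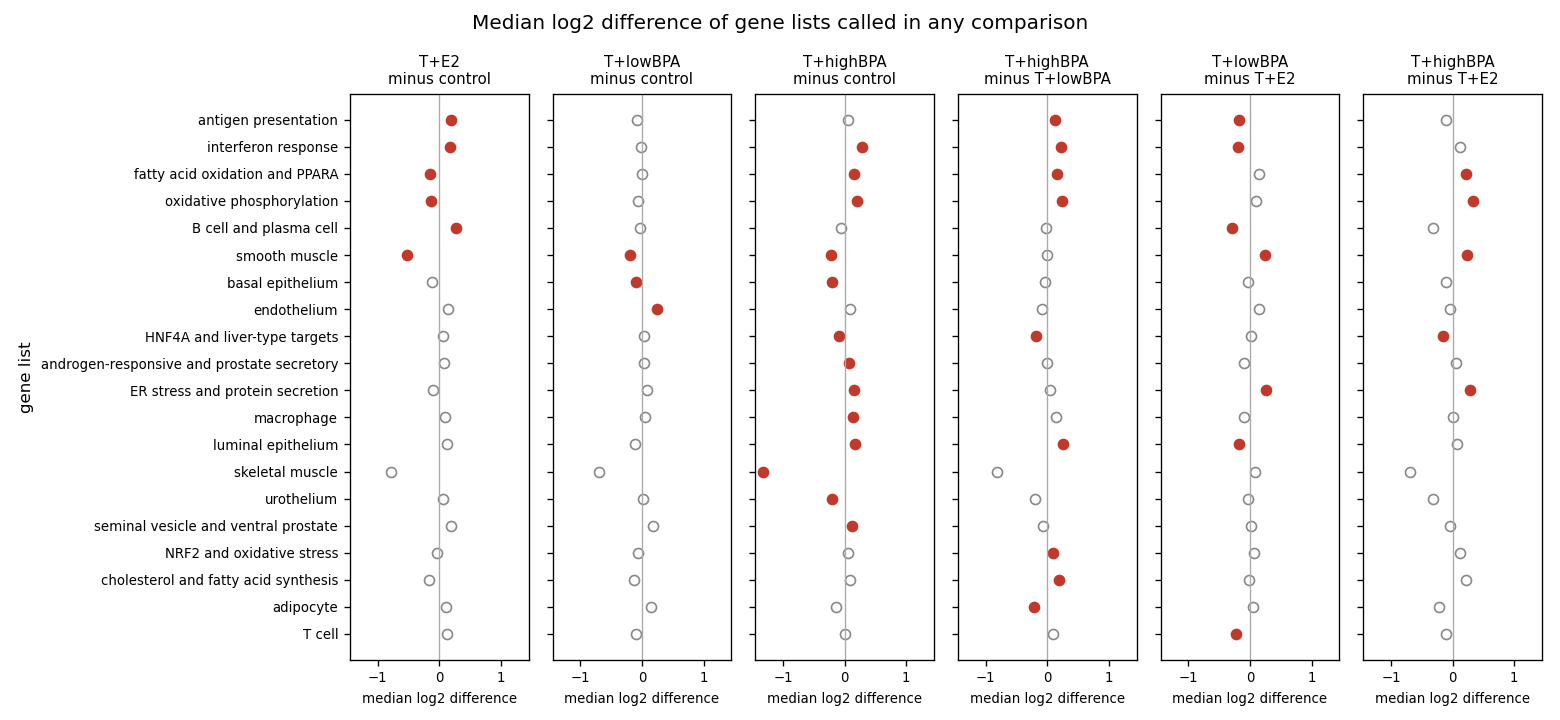
Median log2 difference (x axis) of each gene list called in any comparison (y axis), in 6 panels, 1 per comparison. Filled points are lists with a camera adjusted p below 0.05 at the preset correlation and open points are not; smooth muscle has a median of -0.52 in T+E2 minus control, and 0 lists pass with an estimated correlation.

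Between the BPA groups, 0 genes were called by limma, with 2252 at an unadjusted p below 0.05 and a smallest adjusted p of 0.206. The smallest p values belonged to Ka11 (1.14), Rab13 (0.70) and Agr2 (1.98) among genes higher in T+highBPA, and to Or2av10 (-0.64), Wfikkn1 (-0.52) and Or5g25 (-0.61) among genes lower. None of the 9 index genes was called, and the intervals of the difference stayed wide, from -0.57 to 1.88 for Prlr and from -1.30 to 0.20 for Mki67. Without T+highBPA replicate 1, Ka11 was called (1.34, adjusted p = 0.0347), and without T+highBPA replicate 3, Agr2 (2.56, 0.000765).

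Oxidative phosphorylation was higher in T+highBPA than in T+lowBPA in 27 of 28 members, with a median of 0.24 (adjusted p = 4.24e-09), and interferon response in 30 of 34, with a median of 0.22 (4.28e-07). With an estimated correlation the adjusted p was 0.497 for each. Adjusted over the list alone, 4 interferon genes rose. The skeletal muscle markers, which oxidative phosphorylation followed within groups, had means of 7.01 ± 1.25 in T+highBPA and 7.90 ± 1.64 in T+lowBPA (SD). They were thus lower in T+highBPA, opposite to oxidative phosphorylation, though by less than their spread within the groups. Luminal epithelium and fatty acid oxidation had medians of 0.25 and 0.15 (adjusted p = 6.61e-05 and 0.000403, or 0.497 each with an estimated correlation). The tight junction gene Cldn4 and Krt19 differed by 0.99 and 0.64. Antigen presentation, NRF2 and cholesterol synthesis shifted up (adjusted p = 0.0244, 0.0279 and 0.0442, or 0.792, 0.512 and 0.792 with an estimated correlation), and each call ended under cyclic loess (0.23, 0.208 and 0.322) and quantile normalization (0.225, 0.218 and 0.362). With the ventral prostate mean as a covariate, chosen after seeing the data, cholesterol synthesis turned down (0.0114). Adjusted over the lists alone, 2 NRF2 genes rose, and 0 members changed in the other lists apart from interferon. Adipocyte markers shifted down with a median of -0.21 (adjusted p = 0.0243, or 0.497 with an estimated correlation, and 0.124 with the covariate), and followed skeletal muscle within groups (correlation 0.776). The HNF4A and liver-type list had a median of -0.18, with 32 of 36 members lower (adjusted p = 0.00699, or 0.497 with an estimated correlation), and its call ended under cyclic loess (0.655) and quantile normalization (0.887). Values on the T+highBPA arrays were more widely spread, with an SD over probe sets of 1.90 to 1.91 against 1.78 to 1.84 in T+lowBPA. Without control replicate 4, 0 genes and 11 lists were called. The dimmest genes had a median difference of -0.15 and the brightest 0.06.

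Estradiol, a steroid, and BPA, a bisphenol, were set side by side at the same capsule load of 15 mg with testosterone. Genes that led T+E2 were lower under BPA: Gucy2f was at 3.93 ± 0.14 in T+lowBPA and 10.12 ± 0.29 in T+E2 (SD, limma adjusted p = 1.25e-12). Clca1 was lower in T+lowBPA by 6.17, Adgrg7 by 4.82 and Syt10 by 4.09. Itln1, an intestinal lectin, was at 5.40 ± 0.38 in T+lowBPA and 10.57 ± 0.72 in T+E2 (SD, adjusted p = 0.00187), but at 8.92 ± 2.14 in control, and was not called between T+E2 and control (adjusted p = 0.268). Cdh7 was 9.14-fold higher in T+lowBPA, Ugt2b10 6.20-fold, Nrcam 3.51-fold, Rgsl2h 3.21-fold and Tmeff1 3.19-fold. The count was 569 genes, 287 higher and 282 lower in T+lowBPA. It was 309, 327 and 335 without T+lowBPA replicates 1, 2 and 3 and 882 without control replicate 4, which enters through the shared spread.

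The estrogen receptor gene Esr2 was higher in T+lowBPA than in T+E2 by 0.98 (95% interval 0.48 to 1.47, adjusted p = 0.0308). This call ended without T+lowBPA replicate 1, 2 or 3 (0.112, 0.106 and 0.0955) or T+E2 replicate 1, 2 or 4 (0.0696, 0.0518 and 0.0611). Esr1, Pgr and Prlr were not called, with intervals of -0.06 to 0.34, -0.65 to 0.20 and -2.12 to 0.17. Of 31 estrogen-responsive genes 4 were lower in T+lowBPA, Gata3, Fhl2, Muc1 and Krt19 by 1.08, 0.85, 0.70 and 1.25, while the list was not called (adjusted p = 0.753). Cyp17a1 and Hsd11b2 were lower by 2.79 and 1.79, and Slc7a11 by 2.70. Elf5 and Stat5a were higher by 1.41 and 0.89.

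Antigen presentation, T cell, interferon and B cell lists were lower in T+lowBPA, with medians of -0.18, -0.23, -0.19 and -0.30 (adjusted p = 0.00068, 0.00144, 0.00525 and 0.00525, or 0.972 each with an estimated correlation). The joining chain of antibodies, Jchain, was lower by 1.71 and Cd86, a costimulatory molecule, by 1.15. The call of Cd86 held without control replicate 1 or 4 and ended without any other array (limma adjusted p = 0.0523 to 0.172), and that of Jchain ended without control replicate 3, any T+E2 replicate or T+lowBPA replicate 2 or 3 (0.0506 to 0.177). Luminal epithelium was lower (0.0256), and ER stress and smooth muscle were higher, with medians of 0.26 and 0.25 (0.00207 and 0.00525). The estimated correlation gave an adjusted p of 0.972 for these 3 lists too. Without the 3 arrays highest in ventral prostate genes, a setting chosen after seeing the data, the interferon, luminal and smooth muscle calls ended (0.0659 each). The luminal call also ended with the replicate block (0.075). Over all genes, 1 of 26, 0 of 22, 1 of 34 and 1 of 18 members of the immune lists were lower, and 2, 0, 0 and 4 when adjusted over each list alone, with 1 B cell gene higher. The interferon gene is Herc6, whose call ended without control replicate 2 or 3, T+E2 replicate 1, 2 or 3, T+lowBPA replicate 1 or 3 or T+highBPA replicate 1 (0.0602 to 0.201). Without control replicate 1, 2 antigen presentation genes, 3 interferon genes and 3 B cell genes were lower, and without control replicate 4, 3, 3 and 2, with 1 B cell gene higher. Without T+E2 replicate 1, 2 antigen presentation genes were lower, and without T+highBPA replicate 2 or 3, 1 B cell gene was lower and 1 higher. Of 20 luminal genes 2 were lower and 1 higher (4 and 1 in the list alone), of 19 smooth muscle genes 1 was higher (1), and of 31 ER stress genes 0 (12 higher and 2 lower). The luminal call of Ehf held without control replicate 4, T+E2 replicate 1 or T+lowBPA replicate 3 and ended without any other array (0.0518 to 0.213), and that of Prom1 ended without T+E2 replicate 2 (0.0529) or T+lowBPA replicate 1 or 3 (0.0882 and 0.0851). Without T+E2 replicate 1, 5 luminal genes were lower and 1 higher, and without T+E2 replicate 2 or T+lowBPA replicate 1, 1 was lower and 0 higher. The smooth muscle gene is Hspb6, whose call ended without T+E2 replicate 2 (0.059) or T+lowBPA replicate 3 (0.0718). Without T+E2 replicate 2, 4 lists were called, and without control replicate 4, 7.

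T+highBPA and T+E2 differ in load, 320 mg of BPA against 15 mg of estradiol, so their values are set side by side without matching. Clca1, Gucy2f, Adgrg7, Itln1 and Syt10 were lower in T+highBPA by 7.02, 6.30, 5.21, 4.46 and 4.31. Cdh7 was 8.58-fold higher, Ugt2b10 5.04-fold, Plaat1 3.79-fold and Nol10 3.01-fold, and Derl3 was higher by 1.58. Esr2 was higher by 1.14 (95% interval 0.65 to 1.64, limma adjusted p = 0.00751). Pgr and Mki67 were not called, but were lower by 0.59 and 0.71 without control replicate 4 (0.0317 and 0.0474), and Pgr by 0.79 without T+highBPA replicate 3 (0.0345). The count was 1639 genes, 1045 higher and 594 lower in T+highBPA. It fell to 857, 908 and 1054 without T+highBPA replicates 1, 2 and 3 and to 1040 without T+E2 replicate 1, and was 2493 without control replicate 4.

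Oxidative phosphorylation was higher in T+highBPA than in T+E2 with 6 of 28 members called, among them Ndufa4, Ndufb8 and Uqcrq by 0.56, 0.58 and 0.71, and 15 higher and 1 lower when adjusted over the list alone (adjusted p = 6.96e-07, or 0.677 with an estimated correlation). Without T+highBPA replicate 3, 1 member was called higher and 1 lower, and the calls of Ndufb8, Uqcrq and Ndufs3 ended (limma adjusted p = 0.0591, 0.0675 and 0.0896), that of Ndufs3 also under cyclic loess (0.0502). Fatty acid oxidation had 7 of 25 members higher, with Acaa2 and Decr1 by 1.18 and 0.71, and 10 in the list alone (adjusted p = 0.000225, or 0.559 with an estimated correlation). Without T+highBPA replicate 2 there were 4, and without control replicate 4, 10, beside 9 of oxidative phosphorylation. ER stress and protein secretion had 9 of 31 higher and 1 lower, with the chaperone Hyou1 and Manf higher by 0.96 and 0.74, and 14 higher and 3 lower in the list alone (adjusted p = 0.000199, or 0.559 with an estimated correlation). Without T+highBPA replicate 1, 3 were higher and 1 lower, without T+E2 replicate 1, 4 and 2, without T+E2 replicate 2 or 4 or T+highBPA replicate 2, 5 and 0, without T+highBPA replicate 3, 6 and 0, and without control replicate 4, 13 and 1. Smooth muscle had 4 of 19 higher, led by Tagln with 1.14, and 6 in the list alone (adjusted p = 0.0133, or 0.802 with an estimated correlation). Its call ended under cyclic loess (0.14) and quantile normalization, chosen after seeing the data (0.126). Without T+E2 replicate 2 or T+highBPA replicate 1 or 3, 1 member was called, and without T+E2 replicate 1 or T+highBPA replicate 2, 2. The calls of its members Actg2, Hspb6 and Myl9 ended without T+E2 replicate 2 or T+highBPA replicate 1 or 3 (limma adjusted p = 0.0648 to 0.142) and under cyclic loess (0.0585 to 0.108). That of Hspb6 also ended without T+E2 replicate 1 or 4 or T+highBPA replicate 2 (0.0596 to 0.0907), and that of Myl9 without control replicate 2, T+E2 replicate 1, any T+lowBPA array or T+highBPA replicate 2 (0.0536 to 0.0944). The HNF4A and liver-type list was lower with a median of -0.15 and 2 of 36 members called, Fgb and Alb, at -0.41 and -0.34, and 1 in the list alone (adjusted p = 0.011, or 0.559 with an estimated correlation). This call too ended under quantile normalization (0.752) and cyclic loess (0.635), as did those of Fgb (limma adjusted p = 0.071) and Alb (0.231), and that of Alb also without T+E2 replicate 1, 2 or 4 or T+highBPA replicate 1 or 3 (0.0574 to 0.128). Without control replicate 4, 3 members were lower and 1 higher. Without T+highBPA replicate 3, 9 lists were called, and without control replicate 4, 7. The skeletal muscle mean, which oxidative phosphorylation, fatty acid oxidation and smooth muscle followed within groups, was 7.01 ± 1.25 in T+highBPA and 7.81 ± 1.11 in T+E2 (SD). It was thus lower in T+highBPA, opposite to the shift of these lists, though by less than its spread within the groups.

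Comparisons against control share the control arrays. T+lowBPA and T+highBPA shared 1 called gene, Gpat4, against 0 in simulations of unchanged groups on the same controls and 0 for independent lists. Unchanged groups give almost no calls, so these zeros do not show an overlap beyond that of shared controls. Splitting the controls 2 and 2 left 0 shared calls. The differences of T+lowBPA and T+highBPA from control correlated across genes, which are not independent replicates, at 0.319, against 0.43 simulated, with a covariance of 0.0144 against 0.0123. With the controls split 2 and 2, the correlation ran from -0.264 to 0.178. T+E2 shared 0 called genes with either BPA group. Its correlation was 0.279 with T+lowBPA and 0.049 with T+highBPA against 0.465 simulated for each, with covariances of 0.0158 and 0.0033 against 0.0123. With the controls split, the correlations ran from -0.114 to -0.006 and from -0.335 to 0.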

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

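Among 122 sets of 4 values from the control and T+E2 groups, 10 had a single array far from the other 3, and 5 of these were control replicate 4. Chance alone would set about 1 in 20 such sets apart if they were independent, but several of those flagged share ventral prostate genes. Tests on ventral prostate genes below were chosen after the result was seen. The exception is the position of control replicate 4 over 100 genes picked from all genes. The HNF4A and covariate tests for T+highBPA and the counts over other divisions of the arrays were also chosen afterwards.

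Control replicate 4 stood far above the other controls in the mean of the 9 ventral prostate genes (11.95 against 5.17 to 5.49), in Prlr, the prolactin receptor (9.84 against 7.55 to 7.87), in the mean of the seminal vesicle and ventral prostate list (7.60), of the androgen-responsive and prostate secretory list (9.11) and of cholesterol and fatty acid synthesis (8.74). Control replicate 1 stood above in Adgrg7 (7.04 against 4.79 to 5.11), Ccl25 (5.27) and the mean of interferon response (7.04). Control replicate 3 stood below in Or5g25 (4.10), and T+E2 replicate 1 above in the mean of macrophage markers (8.01). Of the 1668 probe sets without a symbol, which the comparisons did not use, 34 were called in T+E2 minus control, 25 of them higher in T+E2.

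Ventral prostate genes were high in control replicate 4, T+E2 replicate 2 and T+highBPA replicate 2, and raised in T+highBPA replicates 1 and 3 (10.06 and 9.06). Treatment as the whole cause is argued against by arrays of equal treatment, since T+E2 replicate 2 exceeded the mean of the other T+E2 arrays by 5.33. Without the 3 highest arrays, all 9 genes were called higher in T+highBPA than in control, Klk1c9 by 5.44. Those arrays were left out for these same genes, so this is no independent test, and treatment as a part of the cause stays open. Ventral prostate tissue in the dissected samples may be a source. The 100 other genes highest in control replicate 4 were also higher in T+E2 replicate 2, with a median of 1.09 and 97 of 100 positive. Both arrays were singled out for the same ventral prostate genes, so this does not tell tissue from another common cause. A wrong label of control replicate 4 stays open beside ventral prostate tissue, with values on both sides. A scale ran from controls 1 to 3 (0) to T+lowBPA (1), over the 100 genes with the smallest p between these arrays. Control replicate 4 lay at 1.16 and T+highBPA arrays at 0.98 to 1.44, but T+E2 replicate 2 lay at 0.83. Over 100 such genes level in T+E2 replicate 2, control replicate 4 lay at 0.82 and T+highBPA arrays at 0.64 to 0.78. The other controls, each held out in turn, lay at -0.06 to 0.44. Their scales counted control replicate 4 among the controls, so they differ from its own. Over the 14 genes called between T+lowBPA and controls 1 to 3, the median position of control replicate 4 was 0.43, from -0.45 to 1.58. Among them Gk5 (-0.28), Gpat4 (0.25) and Pi4k2b (0.19) were also called with this array counted as a control. That favours positions near the controls, so these 3 genes cannot speak on the label. All 3 lie below the median of 0.43 that includes them and draw it towards the controls. The other genes were not called with this array as a control, which favours positions away from the controls. The median therefore cannot decide on the label.

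On the T+highBPA arrays bright genes were higher and dim genes lower than in T+lowBPA, and the wider spread of values there was weighed as a cause of the list shifts. For oxidative phosphorylation and interferon response it is argued against, because the medians lay at percentile 100 of 10000 lists matched on mean expression, for either list. For HNF4A and liver-type targets the median lay at percentile 7.6, inside the central 95%, so the wider spread may account for that shift. Ventral prostate tissue as a cause of the oxidative phosphorylation shift is argued against by its median of 0.252 with the ventral prostate mean as a covariate, against 0.24 without. That covariate did not overlap between the groups, at 6.44 to 6.68 in T+lowBPA and 9.06 to 12.17 in T+highBPA. The argument therefore holds only if its slope within groups, set largely by control replicate 4 and T+E2 replicate 2, also applies between them. Within groups the oxidative phosphorylation mean followed that of skeletal muscle (correlation 0.884), which was lower in T+highBPA than in T+lowBPA (7.01 and 7.90). The muscle difference thus ran opposite to the oxidative phosphorylation shift. A dose effect of BPA on these lists stays open, and 0 lists passed with an estimated correlation.

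Other divisions of the same arrays were counted for each comparison. For T+E2 minus control, 1 of 35 divisions, the real one, gave as many as 521 genes, and the highest other gave 58. The same held for T+lowBPA minus T+E2 (1 of 35, 569 against 153) and T+highBPA minus T+E2 (1 of 35, 1639 against 611). In these comparisons the real division thus gave more genes than any other. The real division counts itself, so 1 of 35 is the smallest share this test can give. That share was not adjusted over the comparisons, and these comparisons share the T+E2 arrays, so it does not exclude chance. Nor can it separate treatment from another difference common to the T+E2 arrays. For T+lowBPA minus control, 3 of 35 divisions gave at least 3 genes, with a highest other of 30, and chance cannot be excluded. For T+highBPA minus control, 4 of 35 gave at least 1 gene, and chance cannot be excluded. The division that sets control replicate 4 with T+highBPA replicates 1 and 2 gave 453, which points to a structure of the samples other than the groups. For T+highBPA minus T+lowBPA all 10 divisions gave 0 genes or more, the highest other gave 0, and 10 divisions are too few for a share below 0.05.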

How the results depend on the processing

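Quantile normalization, leaving out 3 arrays, and the ventral prostate covariate were chosen after seeing the data; the rest were planned. Of the genes tallied, which are those with the largest changes, index genes and leading called members of called lists, 0 of those called reversed. Their calls were lost in 80 of 642 values for T+E2 minus control, 21 of 75 and 5 of 25 for the BPA groups, and 57 of 445 and 43 of 718 for these minus T+E2. Those not called gained a call in 6, 0, 2, 4, 0 and 9 values and turned sign uncalled in 14, 4, 19, 10, 0 and 20, in the order below. Other list members, such as Fhl2 and Rerg, are outside these counts. The largest changes were chosen among genes without overlap between the groups, so leaving out an array could not reverse them. The values also include settings that change nothing, such as averaging the probe sets of a gene. The cause was not tested unless the setting itself gives it. The precision is set by 3 or 4 arrays per group, and signal over background was not given.

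For the order T+E2, T+lowBPA and T+highBPA minus control, T+highBPA minus T+lowBPA, T+lowBPA and T+highBPA minus T+E2, the genes called were 521, 3, 1, 0, 569 and 1639. Array weights gave 1098, 31, 235, 2, 904 and 2759. With only the compared groups in the fit, which has fewer samples, the first 4 were 222, 0, 0 and 18. The ventral prostate covariate gave 1143, 23 and 80 against control and 881 for T+lowBPA minus T+E2. Without the 3 arrays, T+lowBPA and T+highBPA gave 35 and 25 against control and 6 against each other. For T+lowBPA minus control, genes above the median mean gave 7, all probe sets 5, trend and robust empirical Bayes 8, and quantile normalization 6. An adjusted p below 0.10 gave 861 for T+E2 and 10 for T+lowBPA minus control and 2826 for T+highBPA minus T+E2. Adding a 1.5-fold minimum gave 299 for T+E2 minus control and 777 for T+highBPA minus T+E2. Unadjusted p with 1.5-fold gave 115 and 147 for the BPA groups against control, 210 between them and 974 for T+highBPA minus T+E2. Leaving out 1 array gave 282 to 662, 0 to 14, 0 to 12, 0 to 1, 309 to 882 and 857 to 2493.

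Lists called were 6, 3, 13, 9, 7 and 5 in the same order. With an estimated correlation they were 0 in each, and fry gave 0, 0, 1, 1, 0 and 8. Genes above the median mean gave 3, 5, 8 and 4 in the first 4 comparisons. Array weights gave 6 for T+lowBPA minus control. Quantile normalization gave 7 for T+highBPA minus control. Without the 3 arrays, T+E2 and T+lowBPA minus control gave 1 and 9, and T+lowBPA minus T+E2 gave 4. The covariate gave 11 for T+E2 minus control, 20 for T+highBPA minus control, 16 between the BPA groups and 8 for T+highBPA minus T+E2. Leaving out 1 array gave 1 to 13, 2 to 13, 12 to 19, 7 to 11, 4 to 8 and 5 to 9. The genes shared by T+E2 and T+lowBPA were 0, and 1 at an adjusted p below 0.10; those shared by the BPA groups were 1, and a median of 0 with the controls split.

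Same-numbered pairs correlated from -0.464 to 0.444, with 14 of 19 but not all above 0.1, so the replicate numbers were not taken as a pairing. Every pair of numbers 1 and 3 lay above 0.1, so a component shared by arrays of these numbers is not excluded. The skeletal muscle mean was lower in number 1 than in number 3 in every group. Of the 14 arrays, 6 correlated best with their own number. With the replicate block the genes called were 587, 2, 1, 0, 587 and 1940, and the lists called were 10, 7, 12, 12, 7 and 9.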

Other observations

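All tests of this part were chosen after the leading genes had been seen. Some of the 284 genes raised by T+E2 are of gut and goblet type. A set of 38 such genes was written around those already seen to lead, so its count describes them and tests no enrichment. Of its 35 measured genes 11 were higher and 0 lower in T+E2 than in control, and 9 of the 35 also belong to lists fixed beforehand. Beside Clca1, Clca4 and Ccl25, the fimbrin Pls1 rose 7.09-fold, the protein disulfide isomerase Agr2 6.44-fold, Anxa13 6.24-fold, Vsig1 4.86-fold, Agr3 3.30-fold, the lectin Lgals4 2.99-fold and the transcription factor Klf5 2.46-fold. Under T+lowBPA 0 of the 35 were called against control, and 14 were lower and 1 higher than in T+E2. Agr2 was already at 8.89 ± 0.29 and Klf5 at 9.43 ± 0.24 in control (SD, n = 4).

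Ventral prostate tissue in T+E2 replicate 2 is argued against by the median of 2.39 for the called genes without the 3 arrays, against 2.64 with them. A general rise of dim probe sets on the T+E2 arrays is argued against by a median of 0.034 over all genes at similar control levels. Gut tissue in the T+E2 samples would raise abundant gut transcripts together. The 16 measured of 18 such transcripts had a median difference of 0.12, from -1.54 to 0.24, and 0 were called higher. These transcripts thus did not rise together. That list was written after the leading genes had been seen and left out the called genes, so it does not cover them. Finding 0 called higher was thereby set in advance, and the test cannot decide on gut tissue.

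A run of 9 neighbouring olfactory receptor genes on chromosome 1 of assembly GRCr8, from Or51b17 to Or51i1, was higher in T+E2 than in control in all 9 members. Or51q1 rose 5.29-fold, Or51k1 4.80-fold and Or51b17 1.70-fold, and the median of the run was 1.47. The other 34 Or51 genes had a median of 0.10 with 1 called higher, and 1074 other olfactory receptor genes a median of 0.08 with 7 called higher. In T+lowBPA and T+highBPA these 9 genes differed from control by -0.11 to 0.14 and by -0.31 to 0.01. Neighbouring genes called in the same direction numbered 37 pairs in T+E2 minus control against a mean of 8.5 and a highest of 18 in 1000 permutations of gene order. Among pairs with unlike names there were 24 against a mean of 7.3 and a highest of 17. Probes shared by these similar genes were not examined here.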
